A study of Streptococcus thermophilus CNRZ1066
Lactobacillus delbrueckii subsp. bulgaricus ATCC BAA-365 with 20 samples.

How the data were processed

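The series holds RNA of Streptococcus thermophilus CNRZ1066 and Lactobacillus delbrueckii subsp. bulgaricus ATCC BAA-365, the bacteria that ferment milk to yoghurt, grown in reconstituted skim milk either apart (mono cultures) or together (mixed culture). Per the labels, total RNA was taken after 3.5, 5.5, 8 and 12 h in 2 replicates, and for the mono cultures, RNA of either species grown apart was pooled before labelling, so every labelled sample holds RNA of both species. This gives 16 RNA samples: 2 cultures, 4 times and 2 replicates. They were labelled with Cy3 or Cy5 and hybridised in pairs on 24 arrays of 3 slides with 8 arrays each. GEO lists 20 samples, because in 2 of them 3 arrays each are merged. Of the 24 arrays, 20 pair extracts of the same replicate number and 4 pair extracts of different numbers. The labels call the merged arrays biological replicates but do not say how the 2 replicates of a group were grown; p-values then measure the spread between these extracts only.

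Each scanner file deposited by the authors holds, for 15744 spots, a Cy3 and a Cy5 intensity with its local background, per the file headers as a linear intensity combined over scans (an extended dynamic range signal), with no normalization. The series matrix deposited by the authors holds a linear ratio for each of 8941 probe entries and 20 columns, with no row names beyond a running number. How the authors made it is not given in the sources used here.

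The spots comprise 8054 for S. thermophilus, 7154 for L. bulgaricus and 536 controls, of which 77 are negative controls. The species of a probe was read from the prefix of its identifier (str or LBUL), and the raw ratios of these sets moved apart as blocks on the arrays by up to 4.22 on the log2 scale. The files give locus-style identifiers only and pair them with no gene name or product. The 22 gene lists written beforehand by symbol therefore matched 0 members and were not tested, and no function is named. For the same reason at most 2 identifiers that rose and 2 that fell are printed for a comparison. A feature below means all probes of one identifier. Of the features, 3203 have 3 probes, 212 have 2 and 199 have 1. Among those named below, str_t11, LBUL_1235, LBUL_t0845, LBUL_t0851, LBUL_t0853, LBUL_1087 and LBUL_0960 rest on 1 probe.

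Background was corrected with normexp and an offset of 50 on all spots (limma 3.58.1, R 4.3.3). Within each array, log2 ratios were normalized by loess (span 0.3) on mean intensity, separately for the probes of each species and without control spots. A fold change is therefore relative to the average feature of the same species and says nothing of how much RNA that species gave. Probes whose mean log2 intensity over all arrays did not exceed 6.775, the 95th percentile of the negative controls, were left out, which removed 46 spots. This replaced a filter on a scanner flag for signals well above background, which the files do not hold. Their spot flags (such as empty or negative spot) belong to the single scan and were not used. The same percentile, taken per array and channel, decided whether a probe was above background. Median signals per channel ran from 261.2 to 3132, and those of the negative controls from 44.58 to 104.1. The features named by identifier had a probe above background in every value of both groups compared, except str0978 in mixed against mono over the 4 times, with 22 of 24 values in the lower group. Spots of a probe and then the probes of a feature were averaged, giving 1902 S. thermophilus and 1709 L. bulgaricus features.

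A least-squares fit of the 24 arrays on the 16 RNA samples plus a dye term gave the level of each feature in each extract, with 8 residual degrees of freedom. These levels were tested with limma (lmFit and eBayes) on the 8 groups with the replicate number as a block, with 7 residual degrees of freedom, separately for each species. P-values were adjusted by Benjamini-Hochberg over the features of a species, and features with an adjusted p under 0.05 were called. Comparisons were mixed against mono culture at each time and as the mean of the 4 times, each step between successive times within a culture, and the culture by time interaction. The species balance was the median raw log2 ratio of the L. bulgaricus probes minus that of the S. thermophilus probes, fitted to the 16 samples in the same way and compared by an exact sign-flip test over the 8 time-by-replicate pairs.

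Named features followed a rule that was fixed, with the comparisons and the first set of alternatives, before the data were examined. It takes, among features called with the same sign in both replicates and having a gene symbol or product, those with the highest and the lowest log2 fold change, and where none is called, those with the smallest p. The condition of a symbol or product could not be applied, so the first 2 on each side were taken. For the interaction, the features named for the mean over the 4 times are given. Runs of at least 4 consecutive identifiers called in the same direction were looked at after the first results were seen and compared with 10000 shufflings of the calls over the identifiers. The replicate block was kept as chosen beforehand, and counts without it stand beside the results it moves.

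The procedure was tested, from the fit of the arrays onward, on simulated log ratios of features with the measured spreads. Features were independent, had no effect of the replicate number, and changed equally at all 4 times. Background correction, loess and the filter on dim probes were not tested. For mixed against mono over the 4 times, the procedure recovered 93% of 100 S. thermophilus features changed by 1 on the log2 scale. It recovered 99% of 100 changed by 2, among 1902. For L. bulgaricus, among 1709, it recovered 99% and 100%. At 12 h alone it recovered 51% and 89% for S. thermophilus and 72% and 97% for L. bulgaricus. Among unchanged features it called 7 of S. thermophilus and 13 of L. bulgaricus over the 4 times, and 5 and 7 at 12 h. With 2 extracts per group, the median standard error of a log2 fold change at one time was 0.273 for S. thermophilus and 0.208 for L. bulgaricus.

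Reversing the dye labels of any single array raised the median residual variance of the first fit, by a factor of 1.19 to 3.23, so the channels were taken as labelled. In the series matrix the column medians lay between 0.862 and 1.16. Aligning its 3091 distinct entries in order with the features gave a mean correlation of 0.758 with the sign turned and 0.388 as given, so its values run as Cy3 over Cy5, with S. thermophilus first. The centring stays unknown, and no entry was matched to an identifier. The columns of the 2 replicates of a comparison are reciprocals of each other (log2 values summing to at most 1.5e-07), and all 20 columns close on 8 group values within 9.4e-08. They hold fitted values without replicate spread, so the planned test on them was not run.

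Alternatives tried were no background correction, a single loess over both species, no filter on dim probes, the median of probes, a dye term per slide, no replicate block, a fit of the 24 arrays as independent, leaving out the 4 arrays across replicate numbers and leaving out each extract. Signals of the single scan in the same files, leaving out the features with r, t or s in their identifiers, and leaving out 2 arrays with a low S. thermophilus signal were added after seeing the data.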

Results

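The arrays measured RNA of Streptococcus thermophilus and Lactobacillus bulgaricus grown in milk apart or together. Each of the 8 groups, mono or mixed culture at 3.5, 5.5, 8 and 12 h, had 2 RNA extracts, which makes 16. In these samples 1902 S. thermophilus and 1709 L. bulgaricus features were tested. The files do not pair the identifiers with gene names or products. S. thermophilus probes were above background in 97.4 to 100% of cases per array and channel, except for mono 3.5 h replicate 2 on 2 arrays, where 74% was the lowest share. L. bulgaricus probes were above background in 87.8 to 99.7% in mono RNA and in 57 to 99.7% in mixed RNA. With 2 extracts per group, the p-values rest on a spread pooled over the groups. Features named below as called changed in the same direction in both replicates, and "±" gives the SE of a log2 fold change with n = 2 extracts per group and time.

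The first question was how much of the RNA signal each species gave in mixed culture, compared with the mono culture RNA that the study had pooled. The ratio of L. bulgaricus to S. thermophilus signal was lower in mixed culture at all 4 times and in 8 of 8 pairs of the same time and replicate number. The mean difference was -2.23 ± 0.857 on the log2 scale (SD, n = 8 pairs; two-sided exact sign-flip test, p 0.00781, the smallest this test can give). This is a 4.71-fold lower ratio. The test takes the 8 pairs as independent. The labels do not say whether pairs of the same replicate number share a source. The difference was -1.94 at 3.5 h (replicates -0.805 and -3.07), -1.89 at 5.5 h (-1.88 and -1.91), -3.17 at 8 h (-3.07 and -3.28) and -1.93 at 12 h (-1.62 and -2.25). Arrays that set mixed directly against mono RNA gave -1.71 on the slide used for replicate 1 and -2.49 on the slide used for replicate 2. The mono level depends on the proportion in which the study pooled the mono RNA, which the labels do not give, so the ratio is not one of cell numbers. Single-scan signals, tried after seeing the data, gave -0.895. Leaving out the 2 arrays with a low S. thermophilus signal of mono 3.5 h replicate 2, also tried afterwards, gave -1.71. The value of -3.07 for replicate 2 at 3.5 h rests in part on these arrays. The residual SD of the fit of the balance to the arrays was 0.726 on the log2 scale.

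**Figure D1:**
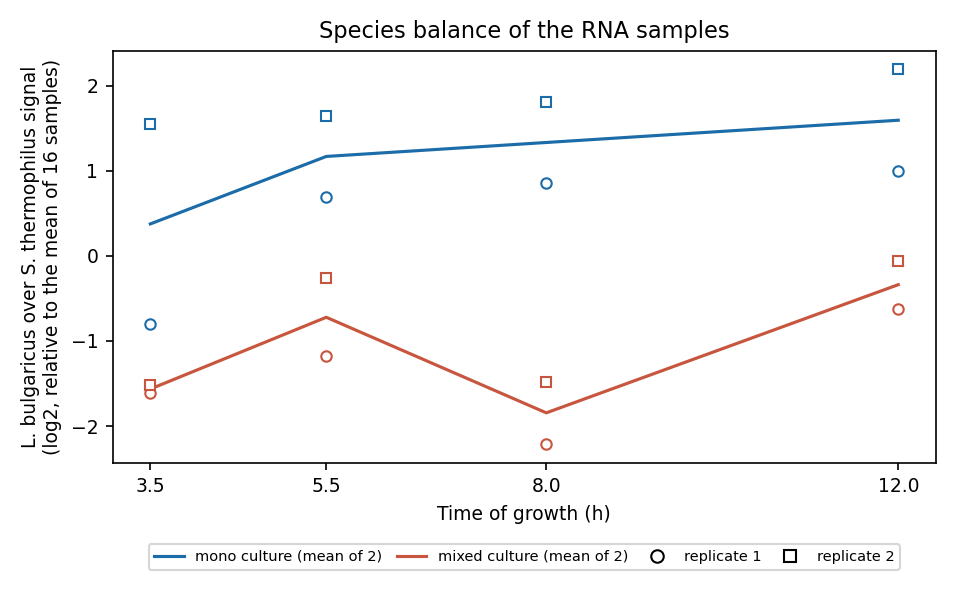
Median L. bulgaricus minus S. thermophilus signal (log2, relative to the mean of the 16 RNA samples) against the time of growth in hours; circles and squares are the 2 replicates and lines their means. The mixed culture means, from -1.84 to -0.339, lie below the mono culture means, from 0.374 to 1.59.

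The next question was which S. thermophilus features differed between mixed and mono culture over the 4 times. The adjacent features str0785 and str0786 fell furthest, with log2 fold changes of -4.59 ± 0.214 and -4.24 ± 0.245 (limma adjusted p 5.85e-07 and 2.18e-06). The highest were str0978 at 1.32 ± 0.176 and str1140 at 1.26 ± 0.144 (adjusted p 0.000782 and 0.000323). A stretch of 9 consecutive identifiers fell by 2.60 on average. With 181 features higher and 236 lower, 417 of 1902 were called, 51 of them at least 2-fold changed. Mean differences on the slides of the 2 replicates had a Pearson r of 0.784 over the 1902 features, which are not independent; slide and replicate number coincide for these arrays. A single normalization of both species together shifted the median of all S. thermophilus features to 0.95 and called 1682 higher and 28 lower, so these directions hold relative to the species' own average. The count was 225 without mono 3.5 h replicate 2, 209 without mono 5.5 h replicate 2, 274 without mono 8 h replicate 1, 255 without mixed 5.5 h replicate 1, 271 without mixed 5.5 h replicate 2, 253 without mixed 8 h replicate 1 and 268 without mixed 12 h replicate 2.

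At 3.5 and 5.5 h few S. thermophilus features were called, nearly all lower in mixed culture relative to the species' average. The features str0785 and str0786 led at both times, at -5.37 ± 0.428 and -5.29 ± 0.489 at 3.5 h (limma adjusted p 7.89e-05 and 0.000179) and at -7.07 ± 0.428 and -6.74 ± 0.489 at 5.5 h (9.11e-06 and 1.64e-05). At 5.5 h the same 9 consecutive identifiers fell by 3.81 on average, and str1325 was higher at 1.26 ± 0.227 (0.016). In all, 13 features were lower and 0 higher at 3.5 h, and 24 were lower and 1 higher at 5.5 h. A single normalization turned this round, with 896 higher and 32 lower at 3.5 h and 667 higher and 23 lower at 5.5 h. Without mixed 3.5 h replicate 1, 123 were higher and 194 lower at 3.5 h. At 3.5 h the count was 6 without mono 3.5 h replicate 1, 5 without mono 3.5 h replicate 2 and 317 without mixed 3.5 h replicate 1. At 5.5 h it was 5 without mono 5.5 h replicate 2, 38 without mixed 3.5 h replicate 2, 9 without mixed 5.5 h replicate 1 and 15 without mixed 5.5 h replicate 2, and the call ended for str1325 in 3 of the 16 omissions. The feature str1325 also lost its call with single-scan signals and with no background correction.

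At 8 h no difference was detected in str0785 and str0786 (-0.12 and -0.20, limma adjusted p 0.851 and 0.778), and other S. thermophilus features differed. The feature str0988 was higher in mixed culture at 3.13 ± 0.581 and str0536 at 2.84 ± 0.896 (limma adjusted p 0.0105 and 0.0492). The features str_r05 and str_t11 were lower at -5.26 ± 0.528 and -4.34 ± 0.766 (adjusted p 0.000809 and 0.00881). At this time 154 features were higher and 202 lower, or 1279 and 13 with a single normalization of both species. The total of 356 rests on few extracts, since it was 236 without mono 5.5 h replicate 2, 9 without mono 8 h replicate 2, 548 without mixed 3.5 h replicate 2, 219 without mixed 5.5 h replicate 1, 6 without mixed 8 h replicate 1 and 181 without mixed 8 h replicate 2, and the call ended for str0988 in 2, str0536 in 11 and str_t11 in 2 of the 16 omissions. The feature str0536 also lost its call with single-scan signals and without the 2 arrays with a low S. thermophilus signal.

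At 12 h 409 S. thermophilus features were higher and 422 lower in mixed culture, the highest count of the 4 times with the species normalized apart. The feature str0297 and its neighbour str0298 fell, with log2 fold changes of -6.71 ± 0.64 and -6.21 ± 0.678 (limma adjusted p 7.58e-05 and 0.000119), within the 9 consecutive identifiers whose mean was -4.81. The features str1140 and str1614 were higher at 3.14 ± 0.289 and 3.12 ± 0.358 (adjusted p 6.71e-05 and 0.000139). A stretch of 14 identifiers was higher by 1.40 on average and another of 13 was lower, at -1.26. A single normalization called 800 higher and 62 lower, 862 in all, fewer than its 1292 at 8 h and 928 at 3.5 h. The count of 831 was 487 without mono 12 h replicate 1 and 390 without mixed 12 h replicate 2. Across features, the differences at 8 h and 12 h hardly went together (Pearson r 0.0587 over 1902 features, which are not independent).

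For L. bulgaricus, the same question gave 248 features higher and 281 lower in mixed culture over the 4 times, or 529 of 1709. The adjacent features LBUL_1236 and LBUL_1235 were highest at 3.47 ± 0.216 and 3.20 ± 0.301 (limma adjusted p 3.31e-06 and 3.65e-05). LBUL_1658 and LBUL_1440 were lowest at -2.04 ± 0.366 and -1.84 ± 0.159 (adjusted p 0.0019 and 2.16e-05). A stretch of 12 consecutive identifiers fell by 1.13 on average. Between the slides of the 2 replicates r was 0.811 over the 1709 features. With a single normalization the median of all L. bulgaricus features moved to -1.16, and 8 features were called higher and 1452 lower. LBUL_1236 and LBUL_1235 stayed higher there at 1.14 and 0.799. In mixed culture LBUL_1236 fell from 3.5 to 5.5 h and rose to 8 h. The species balance of the mixed samples was -1.56, -0.724 and -1.84 at these times, so the S. thermophilus share of the signal moved alike. Whether S. thermophilus RNA bound the probes of these features was not tested. The count was 352 without mono 3.5 h replicate 2 and 300 without mixed 5.5 h replicate 1.

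At 3.5 h 42 L. bulgaricus features were higher and 63 lower in mixed culture, and at 5.5 h 83 were higher and 127 lower. At 3.5 h LBUL_r1682 and LBUL_1236 were higher at 4.72 ± 0.916 and 4.09 ± 0.432 (limma adjusted p 0.0141 and 0.000881), and LBUL_0371 and LBUL_1398 lower at -2.04 ± 0.358 and -1.85 ± 0.228 (0.00967 and 0.0027). At 5.5 h LBUL_t0853 and LBUL_t0851 were higher at 3.27 ± 0.676 and 2.37 ± 0.441 (0.0113 and 0.00878). LBUL_1337 and LBUL_0371 were lower there at -1.84 ± 0.36 and -1.84 ± 0.358 (0.00977 and 0.00971). Of the features called at each time, 70 were called at both, all in the same direction. These counts and their directions depend on the settings. With no replicate block 4 were higher and 0 lower at 3.5 h, and 40 higher and 32 lower at 5.5 h. Single-scan signals gave 13 higher and 16 lower at 3.5 h and 33 higher and 24 lower at 5.5 h, and a single normalization 1 higher and 1059 lower at 3.5 h and 1 higher and 1036 lower at 5.5 h. With extracts left out singly the count at 3.5 h was 12 without mono 3.5 h replicate 2, 212 without mixed 3.5 h replicate 1, 17 without mixed 3.5 h replicate 2 and 33 without mixed 5.5 h replicate 1, and the call ended for LBUL_r1682 in 3 and LBUL_0371 in 2 of the 16 omissions. LBUL_r1682 also lost its call with no replicate block and with a single normalization, LBUL_1236 with a single normalization, LBUL_0371 with no replicate block and with single-scan signals, and LBUL_1398 with no replicate block. For 5.5 h it was 43 without mono 5.5 h replicate 1 (8 higher and 35 lower), 34 without mono 5.5 h replicate 2 and 0 without mixed 5.5 h replicates 1 or 2, and the call ended for LBUL_t0853 in 4, LBUL_t0851 in 4, LBUL_1337 in 3 and LBUL_0371 in 3 of the 16 omissions. LBUL_t0853 and LBUL_t0851 also lost their call with a single normalization, and LBUL_0371 with no replicate block and with single-scan signals.

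At 8 h 232 L. bulgaricus features were higher in mixed culture and 266 lower. LBUL_t0845 and LBUL_1235 were highest at 5.85 ± 0.509 and 5.09 ± 0.603 (limma adjusted p 3.34e-05 and 0.000219), and LBUL_1980 and LBUL_0123 lowest at -3.19 ± 0.264 and -2.94 ± 0.223 (2.78e-05 and 1.8e-05). A stretch of 11 consecutive identifiers, the first 8 of which had been lower at 3.5 and 5.5 h, was now higher by 1.21 on average. A stretch of 12 fell by 1.93 on average. With a single normalization 12 were higher and 1199 lower. The stretch of 11 then turned to -2.14, below the median of all features there (-1.41). LBUL_t0845 and LBUL_1235 stayed higher with it, at 2.37 and 1.54. With no replicate block 123 were higher and 198 lower, and with single-scan signals 156 and 155. The count of 498 was 264 without mono 8 h replicate 1, 272 without mono 8 h replicate 2 (99 higher and 173 lower), 320 without mixed 5.5 h replicate 1 and 165 without mixed 8 h replicate 1.

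At 12 h 356 L. bulgaricus features were higher in mixed culture and 400 lower, 756 in all. LBUL_1658 and LBUL_1440 fell furthest, with log2 fold changes of -7.99 ± 0.731 and -5.72 ± 0.317 (limma adjusted p 6.81e-06 and 2.66e-07). LBUL_1087 and LBUL_0140 were highest at 4.27 ± 0.226 and 3.14 ± 0.185 (1.85e-07 and 4.39e-07). A stretch of 12 consecutive identifiers that includes LBUL_1337 fell by 3.68 on average. Of the features called at 8 h and at 12 h, 274 were called at both, 87.6% of them in the same direction. With a single normalization 37 were higher and 963 lower.

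**Figure D2:**
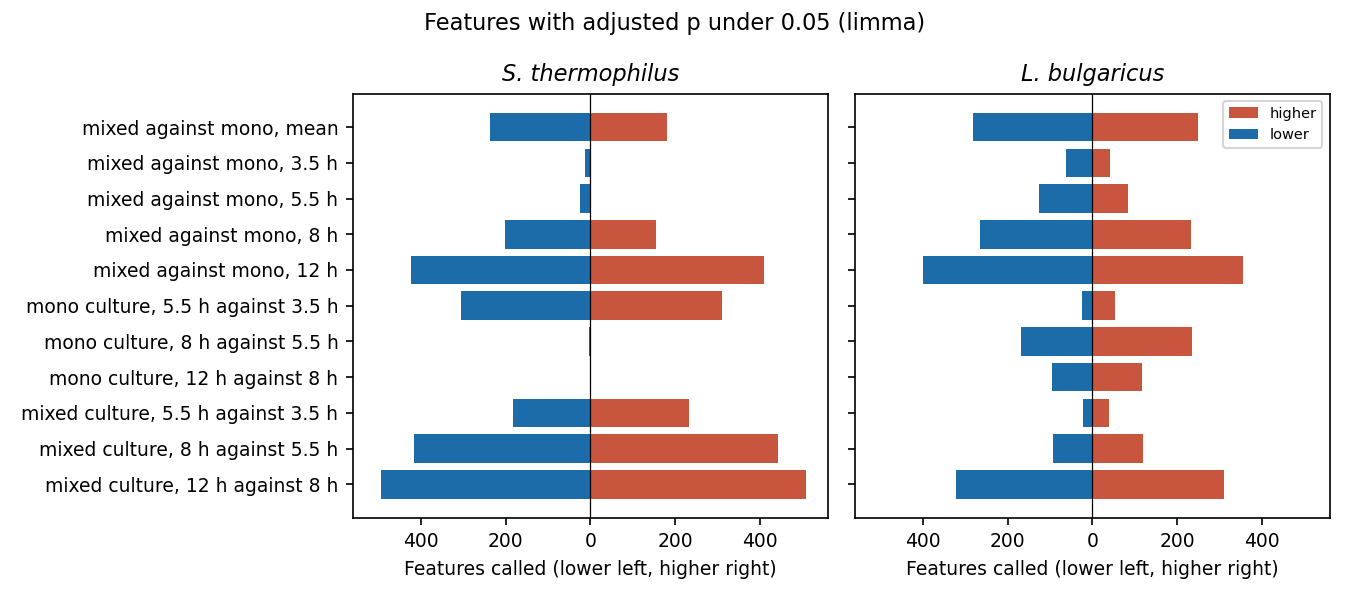
Number of features called (adjusted p under 0.05) for S. thermophilus and L. bulgaricus in each comparison; bars to the left count features lower, and bars to the right features higher, in the group named first. For S. thermophilus the mono culture steps after 5.5 h hold 4 and 0 features, while the mixed culture steps hold 859 and 1004.

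The steps between times ask how each species' expression developed in the course of growth. In S. thermophilus grown alone, expression changed from 3.5 to 5.5 h, with 310 features higher and 305 lower. The features str0792 and str1450 rose by 4.21 ± 0.824 and 4.20 ± 0.877 (limma adjusted p 0.00559 and 0.00678), and str0536 and str1027 fell, with log2 fold changes of -4.71 ± 0.896 and -4.37 ± 0.699 (0.00494 and 0.00241). A stretch of 29 consecutive identifiers fell by 2.26 on average. Single normalization gave 78 higher and 394 lower. The count of 615 was 314 without mono 3.5 h replicate 1, 116 without mono 3.5 h replicate 2, 126 without mono 5.5 h replicate 1 and 172 without mono 5.5 h replicate 2, and the call ended for str0792 in 2, str1450 in 2 and str0536 in 1 of the 16 omissions.

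From 5.5 to 8 h in mono culture 4 S. thermophilus features were called, all lower, led by str1024 at -1.90 ± 0.28 and str1022 at -1.73 ± 0.267 (limma adjusted p 0.0443 for each). This count was 0 without mono 3.5 h replicate 2, mono 5.5 h replicates 1 or 2, mono 8 h replicate 1, mono 12 h replicates 1 or 2, mixed 5.5 h replicates 1 or 2, mixed 8 h replicate 2 or mixed 12 h replicates 1 or 2, 8 without mono 8 h replicate 2, 7 without mixed 3.5 h replicate 1 and 1 without mixed 8 h replicate 1. In 11 of the 16 omissions str1024 lost its call and in 12 str1022, and the count was 0 with a dye term per slide and 2 with a single normalization. The feature str1024 also lost its call with a dye term per slide, and str1022 with single-scan signals, with a single normalization and with a dye term per slide. From 8 to 12 h limma called 0 features in mono culture, with 100 at an unadjusted p under 0.05. The smallest p belonged to str0452 at -2.23 ± 0.404 and str1956 at 1.62 ± 0.299, neither past the threshold (adjusted p 0.209 for each). That count was 1 without mixed 3.5 h replicates 1 or 2.

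In mixed culture S. thermophilus changed at every step. From 3.5 to 5.5 h, str1601 and str1888 rose by 3.29 ± 0.522 and 3.20 ± 0.779 (limma adjusted p 0.00567 and 0.0191), and str1439 and str1440 fell, with log2 fold changes of -2.94 ± 0.606 and -2.93 ± 0.623 (0.0113 and 0.0124). Of the features called, 233 were higher and 183 lower, or 42 and 287 with a single normalization. Of these 416, 276 were also called in mono culture for the same step, all in the same direction. Single-scan signals gave 242. The count was 243 without mono 5.5 h replicate 2, 197 without mixed 3.5 h replicate 1, 0 without mixed 5.5 h replicate 1 and 64 without mixed 5.5 h replicate 2, and the call ended for str1601 in 1, str1888 in 3, str1439 in 2 and str1440 in 3 of the 16 omissions. The features str1439 and str1440 also lost their call with single-scan signals.

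From 5.5 to 8 h in mixed culture 443 S. thermophilus features were higher and 416 lower. The features str0785 and str0987 rose by 6.12 ± 0.428 and 6.04 ± 0.678 (limma adjusted p 1.04e-05 and 0.000344), and str1888 and str1889 fell, with log2 fold changes of -4.17 ± 0.779 and -4.16 ± 0.854 (0.00258 and 0.00377). The stretch of 29 identifiers that fell in mono culture from 3.5 to 5.5 h rose here by 2.63 on average. More broadly, 197 features that had risen in that mono step fell in this mixed step and 202 that had fallen rose, where 67.8 and 71 would be expected if the calls were independent. These steps share no extract. Single normalization gave 519 higher and 180 lower. The count of 859 was 218 without mixed 5.5 h replicate 1 and 454 without mixed 8 h replicate 1, and the call ended for str1889 in 1 of the 16 omissions.

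From 8 to 12 h in mixed culture 509 S. thermophilus features were higher and 495 lower. The features str1614 and str1343 rose by 6.14 ± 0.358 and 4.93 ± 0.405 (limma adjusted p 4.92e-06 and 1.34e-05), and str0297 and str0300 fell, with log2 fold changes of -7.36 ± 0.64 and -7.16 ± 0.721 (1.44e-05 and 2.57e-05). A stretch of 18 consecutive identifiers rose by 2.28 on average and another of 17 fell by 2.24. Single normalization gave 204 higher and 739 lower.

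L. bulgaricus grown alone had features called at each of its steps. From 3.5 to 5.5 h LBUL_1658 and LBUL_0928 rose by 3.34 ± 0.731 and 2.64 ± 0.387 (limma adjusted p 0.0295 and 0.00526), and LBUL_0870 and LBUL_0869 fell, with log2 fold changes of -1.91 ± 0.188 and -1.89 ± 0.184 (0.000419 for each). In all 53 features were higher and 25 lower, 60 and 5 with a single normalization, and 4 and 6 with no replicate block. Single-scan signals gave 70 higher and 56 lower. The count of 78 was 0 without mono 3.5 h replicate 1 or mono 5.5 h replicate 1, 2 without mono 3.5 h replicate 2, 3 without mono 5.5 h replicate 2, 45 without mono 8 h replicate 1 (36 higher and 9 lower), 48 without mono 8 h replicate 2 (38 higher and 10 lower) and 222 without mixed 3.5 h replicate 1 (117 higher and 105 lower), and the call ended for LBUL_1658 in 5, LBUL_0928 in 4, LBUL_0870 in 4 and LBUL_0869 in 3 of the 16 omissions. LBUL_1658 and LBUL_0928 also lost their call with no replicate block.

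From 5.5 to 8 h in mono culture 235 L. bulgaricus features were higher and 169 lower. LBUL_1440 and LBUL_1702 rose by 3.75 ± 0.317 and 3.15 ± 0.34 (limma adjusted p 2.12e-05 and 9.01e-05), and LBUL_0882 and LBUL_1049 fell, with log2 fold changes of -2.13 ± 0.347 and -2.07 ± 0.256 (0.00162 and 0.00023). Single normalization gave 162 higher and 29 lower. The count of 404 was 186 without mono 5.5 h replicate 1, 151 without mono 5.5 h replicate 2, 158 without mono 8 h replicate 1 and 177 without mono 8 h replicate 2 (123 higher and 54 lower).

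From 8 to 12 h in mono culture 116 L. bulgaricus features were higher and 96 lower. LBUL_1496 and LBUL_1497 rose by 3.59 ± 0.489 and 3.49 ± 0.528 (limma adjusted p 0.00165 and 0.00256), and LBUL_1368 and LBUL_0960 fell, with log2 fold changes of -2.48 ± 0.366 and -2.08 ± 0.257 (0.00237 and 0.000961). With no replicate block 76 were higher and 49 lower, and with a single normalization 52 and 11. The count of 212 was 63 without mono 8 h replicate 1 (41 higher and 22 lower), 37 without mono 8 h replicate 2, 104 without mono 12 h replicate 1 (73 higher and 31 lower), 54 without mono 12 h replicate 2 (37 higher and 17 lower), 121 without mixed 5.5 h replicate 1 and 134 without mixed 5.5 h replicate 2, and the call ended for LBUL_1368 in 1 of the 16 omissions.

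In mixed culture few L. bulgaricus features were called from 3.5 to 5.5 h. LBUL_0737 and LBUL_1264 rose by 3.20 ± 0.363 and 2.37 ± 0.495 (limma adjusted p 0.00177 and 0.0357), and LBUL_1236 and LBUL_1235 fell, with log2 fold changes of -2.64 ± 0.432 and -2.55 ± 0.603 (0.0129 and 0.0481). Of the features called 38 were higher and 22 lower, or 82 and 0 with a single normalization. With no replicate block 2 were higher and 0 lower, and with single-scan signals 3 and 2. The count of 60 was 8 without mono 3.5 h replicate 1, 11 without mono 3.5 h replicate 2, 12 without mono 5.5 h replicate 1, 13 without mono 5.5 h replicate 2, 21 without mono 8 h replicate 1 (10 higher and 11 lower), 18 without mono 8 h replicate 2, 22 without mixed 3.5 h replicate 1 (11 higher and 11 lower), 1 without mixed 5.5 h replicate 1, 2 without mixed 5.5 h replicate 2 and 27 without mixed 8 h replicate 1, and the call ended for LBUL_0737 in 1, LBUL_1264 in 10, LBUL_1236 in 4 and LBUL_1235 in 13 of the 16 omissions. LBUL_1264 also lost its call with no replicate block and with single-scan signals, LBUL_1236 with no replicate block, with single-scan signals, with a single normalization, without the 4 arrays across replicate numbers and without the 2 arrays with a low S. thermophilus signal, and LBUL_1235 with no replicate block, with single-scan signals, with a single normalization, with the median of probes, without the 4 arrays across replicate numbers and without the 2 arrays with a low S. thermophilus signal.

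From 5.5 to 8 h in mixed culture 119 L. bulgaricus features were higher and 93 lower. LBUL_t0845 and LBUL_1236 rose by 4.58 ± 0.509 and 3.78 ± 0.432 (limma adjusted p 0.000291 and 0.000352), and LBUL_0726 and LBUL_0927 fell, with log2 fold changes of -2.76 ± 0.182 and -1.91 ± 0.473 (9.15e-06 and 0.0231). A stretch of 29 consecutive identifiers rose by 1.87 on average. With no replicate block 45 were higher and 26 lower, with single-scan signals 35 and 6, and with a single normalization 12 and 286. The count of 212 was 16 without mixed 5.5 h replicate 1, 79 without mixed 5.5 h replicate 2 (67 higher and 12 lower) and 26 without mixed 8 h replicate 1 (23 higher and 3 lower), and the call ended for LBUL_0927 in 3 of the 16 omissions. LBUL_0927 also lost its call with no replicate block and with single-scan signals.

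From 8 to 12 h in mixed culture 311 L. bulgaricus features were higher and 321 lower. LBUL_1157 and LBUL_1550 rose by 4.97 ± 0.49 and 4.23 ± 0.232 (limma adjusted p 2.43e-05 and 4e-07), and LBUL_t0845 and LBUL_1337 fell, with log2 fold changes of -6.12 ± 0.509 and -5.33 ± 0.36 (7.01e-06 and 1.22e-06). A stretch of 12 consecutive identifiers around LBUL_1337 fell by 4.35 on average. Single normalization gave 627 higher and 52 lower, and single-scan signals 397 in all. The count of 632 was 386 without mixed 8 h replicate 1.

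Called features lay in runs of consecutive identifiers more often than shuffled calls did, except for S. thermophilus at 3.5 h and in the later mono steps, where 12, 4 and 0 coding features were called and 0 lay in runs. Over the 4 times, 95 called S. thermophilus features lay in 20 runs of at least 4 with the same direction, against 1.58 features on average and 17 at most in 10000 shufflings (permutation p 1e-04, the smallest they can give). At 12 h 395 lay in 65 runs, against 23.4 on average. For L. bulgaricus 65 lay in 12 runs over the 4 times, against 4.63 on average, and 281 in 48 runs at 12 h, against 20.4 (permutation p 1e-04 for each). Identifiers are taken here in numerical order, since the files give no positions.

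**Figure D3:**
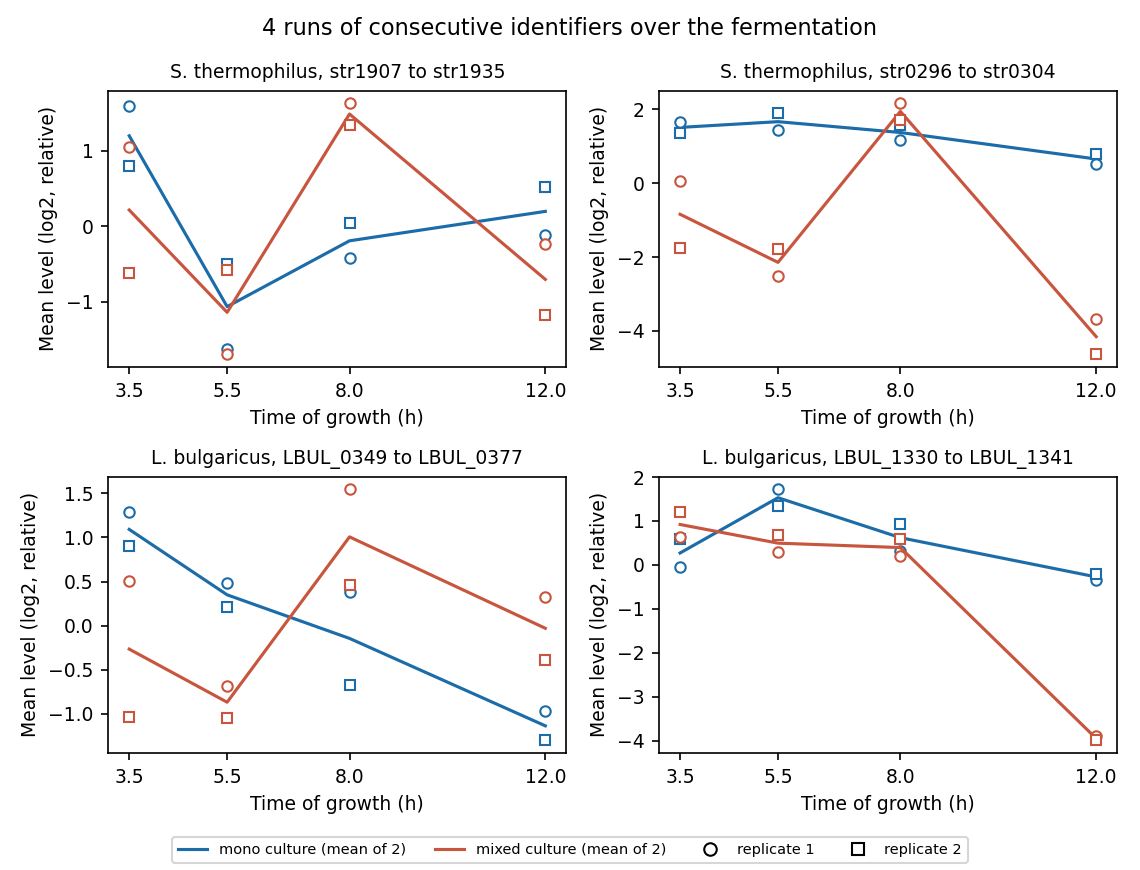
Mean log2 level of 4 runs of consecutive identifiers, chosen after their values were seen, against the time of growth in hours; circles and squares are the 2 replicates, lines their means, and levels are relative to the species' average. The run of 9 S. thermophilus identifiers lies lower in mixed culture at 3.5, 5.5 and 12 h, at differences of -2.35, -3.81 and -4.81. It does not at 8 h, where the difference is 0.57. At 3.5 h its members were not called as a run.

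The interaction test asks whether the difference between the cultures changed with time. It called 718 of 1902 S. thermophilus and 788 of 1709 L. bulgaricus features (limma, adjusted p under 0.05). For str0785 and str0786 the adjusted p was 0.000525 and 0.00171, and for LBUL_1658 and LBUL_1440 it was 0.000118 and 8.74e-06. The S. thermophilus count was 397 without mono 3.5 h replicate 2, 422 without mono 5.5 h replicate 2, 418 without mono 8 h replicate 2, 423 without mono 12 h replicate 1, 434 without mixed 5.5 h replicate 1, 430 without mixed 8 h replicate 1, 455 without mixed 8 h replicate 2 and 358 without mixed 12 h replicate 2, and 438 with a single normalization.

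Features whose identifiers carry an r or t had medians in opposite directions in the 2 species; they were not tested as a class. The median over 33 such S. thermophilus features was -0.959 over the 4 times, with 18 called lower and 0 higher in mixed culture. The median over 44 L. bulgaricus ones was 0.869, with 29 called higher and 0 lower. It did not hold for all of them at each time: the 15 L. bulgaricus features with an r had medians of -0.29 at 8 h and -0.224 at 12 h, the 5 of S. thermophilus had 0.518 at 3.5 h and 0.178 at 5.5 h, and at 12 h the L. bulgaricus median over all 44 was 0.967 in replicate 1 and -0.333 in replicate 2. With a single normalization, which moved the medians of all features to 0.95 and -1.16, these medians were -0.0509 and -0.838. The L. bulgaricus direction thus turned and the S. thermophilus difference nearly vanished. Both hold only relative to the species' average.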

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

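Of the tests given in this part, the relation of the r and t features to the species balance and the splits even over the replicate numbers were chosen only after the result was seen, and the form of the covariance test for S. thermophilus was changed from a ratio to a difference after the ratio proved meaningless.

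The difference between mixed and mono culture changed with time in 718 S. thermophilus and 788 L. bulgaricus features (limma interaction test, adjusted p under 0.05). Among named features, the adjusted p was 0.0136 for str0978, 0.00338 for str1140, 0.000525 for str0785 and 0.00171 for str0786. It was 0.00861 for LBUL_1236, 0.016 for LBUL_1235, 0.000118 for LBUL_1658 and 8.74e-06 for LBUL_1440. Their means over the 4 times therefore hide unlike values: str0785 was lower in mixed culture at 3.5, 5.5 and 12 h by -5.37, -7.07 and -5.78, and at -0.12 at 8 h.

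Control spots that the comparisons do not use also gave signal. Of 459 control spots other than the negative controls, 223 lay above the 95th percentile of the negative controls. Most of these, 158, were among the 200 spots named (+)E1A, whose plus sign sets them against the negative controls, named with a minus. Of the 35 spots named DarkCorner, 0 lay above. The median of all 459 was 6.76 on the log2 scale, against 10.1 for spots of the bacteria.

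For mixed against mono culture over the 4 times, fewer than 5% of the splits drawn called as many features as the real one. In 1 of the draws below this held only narrowly. Chance is not excluded, since not every possible split was drawn and other splits keep some of the culture differences. For S. thermophilus 2 of 100 splits of the 16 samples within the times, the real one included, called as many features as the real 417. The highest other split called 585; it kept the cultures apart at all 4 times with 8 h turned round, which points to the interaction with time. For L. bulgaricus only the real split, 1 of 100, called as many as 529, and the highest other called 365. Splits that follow the replicate number, 8 of 648 possible, were left out, and the others need not part the replicate numbers evenly at each time as the real one does. Among 100 drawn from the 128 splits that part the replicate numbers evenly at each time, 4 called as many for each species, the real one included, and the highest others called 585 and 717.

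The first pattern weighed is that L. bulgaricus features with r or t in their identifiers had a median above 0 for mixed against mono culture (0.869) and those of S. thermophilus below 0 (-0.959). The L. bulgaricus median did not fall when the dim features were left out. Most features were kept, so this test could hardly have turned out otherwise. The 38 of 44 L. bulgaricus features brighter than the species' median had a median of 1.09 (interval 0.737 to 1.57). This interval and those for the patterns below come from resampling features, which are not independent. They do not cover the spread between extracts. RNA of the other species on conserved probes could also give this pattern, since the share of L. bulgaricus in the signal was lower in mixed RNA, and would make the L. bulgaricus level fall and the S. thermophilus level rise with that share. Over the 8 mono samples Pearson r was -0.121 for L. bulgaricus (exact permutation p 0.774, adjusted 0.907 over 4 relations; Spearman 0.0476, exact p 0.935; r 0.0866 without the 2 farthest samples, -0.49 to 0.47 on leaving out 1) and 0.752 for S. thermophilus (exact p 0.0359, adjusted 0.144; Spearman 0.81, exact p 0.0218; r 0.482 without the 2 farthest, 0.697 to 0.817 on leaving out 1), and over the 8 mixed samples it was -0.5 (exact p 0.209, adjusted 0.418; Spearman -0.643, exact p 0.0962; r -0.00103 without the 2 farthest) and 0.0479 (exact p 0.907, adjusted 0.907). None passed adjustment. With 8 samples each and unlike values for the species and cultures this explanation stays open. An effect of the culture cannot be told apart from it. Coding features such as LBUL_1236 and LBUL_1235 were not examined for it.

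The second pattern is that more L. bulgaricus features differed between the cultures at 12 h (756) than at 3.5 h (105). Features below background do not explain it. Among 1164 features above background on every array, 559 were called at 12 h and 101 at 3.5 h. Their ratio was 5.53 (4.58 to 6.77). Weak signals above background were not tested, so low L. bulgaricus signal in mixed RNA is not excluded. A larger independent spread between replicates at 3.5 h does not explain the pattern. The covariance of the replicates' differences over features was 4.03 times as large at 12 h (3.34 to 4.86). Errors common to both replicates are not excluded, since arrays at both times paired extracts of different replicate numbers. The pattern holds only relative to the species' average, since a single normalization called 1060 at 3.5 h and 1000 at 12 h, and with the species normalized apart the count at 3.5 h ran from 4 with no replicate block to 456 with the 24 arrays taken as independent. No biological explanation was tested, and the design does not separate an effect of the other species from a culture further along in growth.

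The third pattern is that S. thermophilus changed after 5.5 h in mixed culture (859 and 1004 features) and hardly in mono culture (4 and 0). A different spread between replicates does not explain the larger mixed culture change from 8 to 12 h. The covariance of the replicates' changes was 1.95 in mixed and -0.0361 in mono culture. The first less 1.5 times the second had an interval of 1.81 to 2.21. The replicate noise SD over features was 0.51 in mixed and 0.582 in mono culture. The mono replicates' changes did not go together there (Pearson r -0.119), so smaller mono changes may be hidden. The step from 5.5 to 8 h was not tested in this way. The low S. thermophilus signal of mono 3.5 h replicate 2 on 2 arrays is not the source of the early mono step, since without them 615 features were called there, and 2 and 0 in the later steps. A candidate explanation is that the mono culture had reached a steady state by 5.5 h while the mixed culture changed again after it. Growth data that would test this are not among the files.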

How the results depend on the processing

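Among the tests of processing in this part, single-scan signals, leaving out 2 arrays with a low S. thermophilus signal, and leaving out the r, t and s features were chosen only after the data were seen.

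The species balance stayed below 0 under every alternative run, from -2.43 with no background correction to -0.895 with single-scan signals. Counts within 1.5 times those reported are not listed. The filter on dim probes, the median of probes, and leaving out the r, t and s features moved no count further than that. Taking the 24 arrays as independent gave for S. thermophilus 771 (mixed against mono overall), 537 (mixed against mono at 3.5 h), 195 (mixed against mono at 5.5 h), 970 (mixed against mono at 8 h), 1278 (mixed against mono at 12 h), 1004 (mono culture 5.5 h after 3.5 h), 92 (mono culture 8 h after 5.5 h), 10 (mono culture 12 h after 8 h), 818 (mixed culture 5.5 h after 3.5 h), 1590 (the interaction) and for L. bulgaricus 456 (mixed against mono at 3.5 h), 524 (mixed against mono at 5.5 h), 797 (mixed against mono at 8 h), 157 (mono culture 5.5 h after 3.5 h), 373 (mono culture 12 h after 8 h), 192 (mixed culture 5.5 h after 3.5 h), 386 (mixed culture 8 h after 5.5 h), 1292 (the interaction). A single loess over both species gave for S. thermophilus 1710 (mixed against mono overall), 928 (mixed against mono at 3.5 h), 690 (mixed against mono at 5.5 h), 1292 (mixed against mono at 8 h), 2 (mono culture 8 h after 5.5 h), 438 (the interaction) and for L. bulgaricus 1460 (mixed against mono overall), 1060 (mixed against mono at 3.5 h), 1037 (mixed against mono at 5.5 h), 1211 (mixed against mono at 8 h), 191 (mono culture 8 h after 5.5 h), 63 (mono culture 12 h after 8 h). No background correction gave for S. thermophilus 23 (mixed against mono at 3.5 h) and for L. bulgaricus 304 (mixed against mono at 3.5 h), 340 (mixed against mono at 5.5 h), 352 (mixed culture 8 h after 5.5 h). Single-scan signals gave for S. thermophilus 242 (mixed culture 5.5 h after 3.5 h) and for L. bulgaricus 29 (mixed against mono at 3.5 h), 57 (mixed against mono at 5.5 h), 311 (mixed against mono at 8 h), 126 (mono culture 5.5 h after 3.5 h), 5 (mixed culture 5.5 h after 3.5 h), 41 (mixed culture 8 h after 5.5 h), 397 (mixed culture 12 h after 8 h). Leaving out the 2 arrays with a low S. thermophilus signal gave for S. thermophilus 2 (mono culture 8 h after 5.5 h) and for L. bulgaricus 187 (mixed against mono at 3.5 h), 22 (mixed culture 5.5 h after 3.5 h). Leaving out the 4 arrays across replicate numbers gave for L. bulgaricus 33 (mixed culture 5.5 h after 3.5 h). A dye term per slide gave for S. thermophilus 0 (mono culture 8 h after 5.5 h). Arrays that share an extract are not independent, so the first of these overstates the evidence. A single loess does not centre each species apart. For mixed against mono over the 4 times it moved the medians of all features to 0.954 for S. thermophilus and -1.16 for L. bulgaricus. How much of its counts this accounts for was not tested. For the remaining alternatives the cause was not tested either.

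Leaving out the replicate block moved no S. thermophilus count by more than 1.5 times. For L. bulgaricus, with no replicate block, the counts were 4 (mixed against mono at 3.5 h), 72 (mixed against mono at 5.5 h), 321 (mixed against mono at 8 h), 10 (mono culture 5.5 h after 3.5 h), 125 (mono culture 12 h after 8 h), 2 (mixed culture 5.5 h after 3.5 h), 71 (mixed culture 8 h after 5.5 h). The correlation of replicate differences exceeded 0.1 in 23 of 28 pairs of groups for L. bulgaricus (median 0.32, from -0.23 to 0.63) and in 9 of 28 for S. thermophilus (median 0.059, from -0.4 to 0.64). The species balance was also higher in replicate 2 in all 8 groups. This and the L. bulgaricus values could reflect an effect shared by samples of 1 number. They could also come from the layout of the arrays. Extracts of the 2 numbers were linked only by the 4 arrays across replicate numbers, so an error there enters all 8 replicate differences alike. The 8 groups are thus not 8 separate observations. The labels name no source of a shared effect and some pairs lack it. Whether the numbers pair the samples therefore stays open, also for the pairs in the balance test.

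With 1 extract left out, its group keeps a lone sample that is assumed to vary like the others. Counts then ran, for S. thermophilus, 209 to 520 (mixed against mono overall), 5 to 317 (mixed against mono at 3.5 h), 5 to 38 (mixed against mono at 5.5 h), 6 to 548 (mixed against mono at 8 h), 390 to 923 (mixed against mono at 12 h), 116 to 726 (mono culture 5.5 h after 3.5 h), 0 to 8 (mono culture 8 h after 5.5 h), 0 to 1 (mono culture 12 h after 8 h), 0 to 577 (mixed culture 5.5 h after 3.5 h), 218 to 957 (mixed culture 8 h after 5.5 h), 701 to 1093 (mixed culture 12 h after 8 h), 358 to 973 (the interaction). For L. bulgaricus they ran 300 to 512 (mixed against mono overall), 12 to 212 (mixed against mono at 3.5 h), 0 to 313 (mixed against mono at 5.5 h), 165 to 507 (mixed against mono at 8 h), 512 to 747 (mixed against mono at 12 h), 0 to 222 (mono culture 5.5 h after 3.5 h), 151 to 448 (mono culture 8 h after 5.5 h), 37 to 241 (mono culture 12 h after 8 h), 1 to 77 (mixed culture 5.5 h after 3.5 h), 16 to 268 (mixed culture 8 h after 5.5 h), 386 to 659 (mixed culture 12 h after 8 h), 548 to 852 (the interaction). The species balance ran from -2.41 to -1.89.

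The named features turned direction in 0 of 2179 alternatives over 81 comparisons, lost their call in 160 and gained it in 4. Those called had been picked for large changes with the same sign in both replicates. Few turns could therefore occur when extracts were left out singly, and their absence is no independent support. Of 972 alternatives of run means, 842 moved less than the replicate spread, 125 moved further and 5 turned. All those that turned were L. bulgaricus under a single loess: runs of 23 (12 h, -0.0408), 11 (8 h, -2.14) and 5 identifiers (3.5 h -0.292, 5.5 h -0.281, over the 4 times -1.47), and the median of the r and t features (-0.838). Each moved further than the median of all L. bulgaricus features did, and the run of 11 and the run of 5 over the 4 times ended below that median (-1.41 and -1.16). The cause was not tested.

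The test planned on the series matrix was not run, because its values hold no replicate spread. Tests of gene lists, and so their estimated correlation, were not run for want of gene names. Signal over background limits L. bulgaricus most, in mixed RNA, where as few as 57% of probes were above background.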

Other observations

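The counts of series matrix entries given in this part were chosen only after the data were seen.

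In the series matrix deposited by the authors, the columns of the 2 replicates of a comparison are reciprocals of each other, with log2 values that sum to at most 1.5e-07. At 12 h mixed against mono, 40.3% of its 1869 distinct S. thermophilus entries and 39.2% of its 1222 distinct L. bulgaricus entries were at least 2-fold changed. Of the 1902 and 1709 features measured from the scanner files it was 31.7% and 24%. From 8 to 12 h in mono culture the S. thermophilus shares were 3.53% and 2.05%. No entry was matched to an identifier, so these shares cover unlike sets and do not show that the processing differs.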
